A study of Mus musculus with 6 samples.

How the data were processed

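Gene expression was measured in tumour cells sorted from mouse lungs. MVT1, a mouse mammary tumour line that forms lung metastases, carried green fluorescent protein (GFP), and 3000000 cells were given to each FVB/N mouse through a vein. From 1 week after injection, mice received daily by gavage either vehicle or GW2580, a small-molecule inhibitor of the CSF1 receptor kinase, at 160 mg per kg. The receptor is made chiefly by macrophages and their precursors. GFP-positive cells were sorted at 1 and at 2 weeks, and biotin-labelled cRNA made from 2 µg of total RNA was hybridised to Affymetrix whole-genome mouse arrays, which carry short oligonucleotide probe sets. The 6 arrays form 3 groups of 2: vehicle at 1 week, vehicle at 2 weeks and GW2580 at 2 weeks. Per the design text, each vehicle group came from 2 mice. How many mice stood behind each GW2580 array is not given in the sources used here, so its spread may be technical.

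The values are log2 expression values that the authors made with RMA, per the submitters' processing notes, and deposited as a single table of 45101 probe sets. RMA corrects the background, quantile-normalises the probes across arrays and summarises them per probe set. Its version and the probe set definitions are not given in the sources used here. Quantile normalisation gives all arrays nearly the same distribution, so a shift shared by most genes cannot be seen. Array medians lay between 5.57 and 5.63 and maxima between 14.6 and 14.7. Arrays give no read depth, and their number limits the precision.

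The 64 control probe sets were left out of the tests. Of the other 45037, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 had none there. By gene identifier, 34741 of the 34945 matched the RefSeq gene table of GRCm38.p6, and the update changed 0 symbols. For each of 18193 genes, the probe set with the highest mean over the 6 arrays was kept; 9010 genes had more than 1. Genes below a mean of 4.97, the 40th percentile over all non-control probe sets, were left out, and 13090 genes were tested. No genome sequence was used here, so no positions are given.

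The test was limma (version 3.58.1, in R 4.3.3): lmFit with a mean for each of the 3 groups over all 6 arrays, then eBayes without trend and not robust. The fit had 3 residual degrees of freedom, 4.97 prior degrees of freedom and a prior SD of 0.147 log2 units. P-values were adjusted by the Benjamini-Hochberg method over the 13090 genes of a comparison, and a gene was called at an adjusted p under 0.05. Every adjusted p for a gene is from this fit, unless another fit is named beside it. A permutation test of 2 arrays against 2 cannot give a two-sided p below 0.333, so none was used. Errors of log2 differences are standard errors (SE) from limma.

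There were 25 gene lists, fixed before the data were examined: 8 of cell type markers (macrophage and monocyte, neutrophil, lymphocyte and NK cell, lung epithelium, endothelium, fibroblast and smooth muscle, erythroid and platelet, mammary epithelium) and 17 of pathways. Each was tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 25 lists of a comparison. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance in a single direction, were the alternatives. Members called over all genes tested are given beside the number called when p was adjusted over the list alone. A listed gene without a probe set of its own symbol, or below the filter, was not analysed here.

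The rule for named genes was also fixed before the data were examined. For the time and the inhibitor comparison it took the 8 largest rises and 8 largest falls among called genes whose groups did not overlap, and up to 4 called members of each list, or up to 2 with the smallest p where none was called. It always took Csf1r, Csf1, Il34, Myc, Vegfa, Epcam and Ptprc. For GW2580 against 1 week, it took 3 genes in each direction. Genes named outside this rule are said to be chosen after their values were seen.

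The procedure was tested on simulated arrays with 200 of 13090 genes changed. In the time comparison it recovered 73.7% of genes changed 2-fold and 98.6% of those changed 4-fold, but 9.0% of those changed 1.5-fold. In the inhibitor comparison these shares were 72.7%, 99.1% and 10.4%, and 5.6% of its calls were false. Camera at the preset correlation called 3 of 440 unchanged lists and 60 of 60 lists shifted by 0.5 log2. Simulated genes varied independently of each other, so these rates do not hold for genes that move together. In the data the estimated correlation was, for example, 0.615 for cell cycle and 0.657 for immediate early genes.

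Both main comparisons use the 2-week vehicle arrays, so unchanged groups sharing those arrays were simulated 100 times. The simulated genes varied independently of each other, so the simulated ranges may be too narrow for genes that move together. Alternatives set before the data were examined were other filters, quantile normalisation or a common 75th percentile, an intensity trend, a robust prior, only the 4 arrays compared, replicate number as a block, other probe set rules, all probe sets, a 2-fold minimum, array weights, and each array left out in turn. The median of each list under quantile normalisation, the common 75th percentile and without each array was added after the data were seen, as were simulations of unchanged groups for each array left out. With an array left out, the lone array of its group is assumed to vary like the others.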

Results

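The study asked how the expression profile of metastatic mammary tumour cells in the lung differs between an early and a later stage, and between later-stage mice given a CSF1 receptor inhibitor and mice given vehicle. Levels are RMA log2 values, and groups are given as mean ± SD with n = 2 arrays. Over all genes, arrays of a group correlated at r = 0.992 (1-week vehicle), 0.992 (2-week vehicle) and 0.988 (GW2580) on the tested values. Over all probe sets the 2 GW2580 arrays correlated at 0.9924 with each other. With replicate 2 of the 1-week group they correlated as closely, at 0.9925 and 0.9928. Control probe sets set 2 arrays apart. On replicate 2 of the 2-week vehicle group the 3' probe set of beta-actin exceeded the 5' one by 1.20 log2 units, against 0.38 to 0.50 on the other 5 arrays. On replicate 1 of the 1-week group the BioB hybridization control read 10.03, against 8.74 to 9.02 elsewhere. RNA spiked in before labelling (mean of 8 probe sets) read 8.49 and 8.52 on the 1-week arrays and 8.86 to 9.24 on the 2-week arrays.

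**Figure D1:**
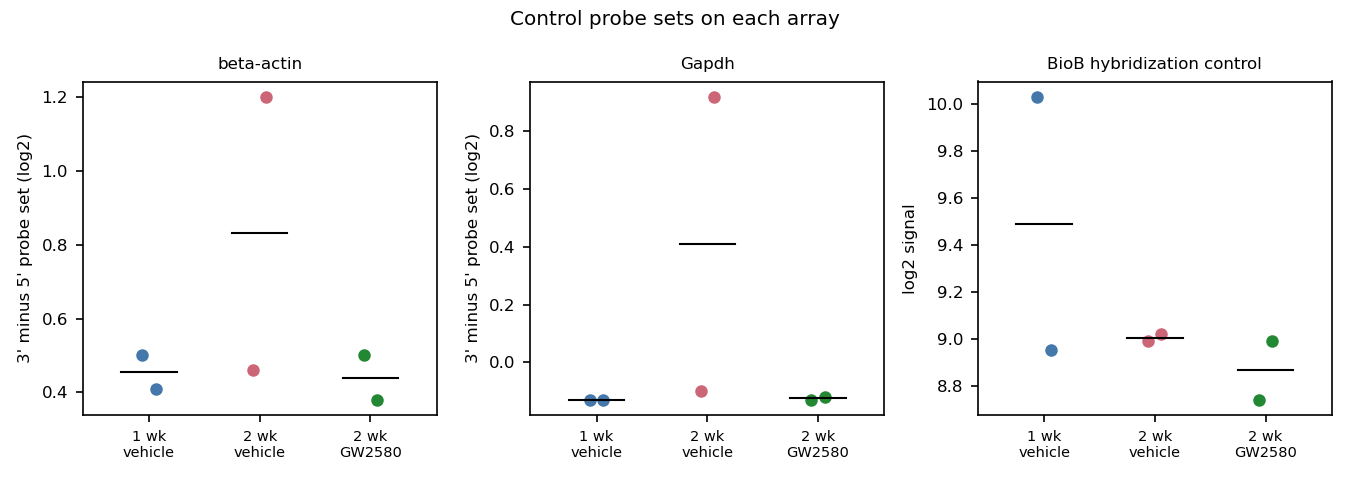
Control probe sets on each array (points, 2 per group; black line, group mean): 3' minus 5' signal of beta-actin and of Gapdh, and the BioB hybridization control, all in log2 units. Replicate 2 of the 2-week vehicle group stands at 1.20 for beta-actin and 0.92 for Gapdh, and replicate 1 of the 1-week group at 10.03 for BioB.

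The comparison of vehicle arrays at 2 weeks with those at 1 week addressed the change of tumour cells as metastases grew. Daily gavage, begun 1 week after injection, also lay between these groups. The 4 largest rises of the genes named by the rule were in genes of secreted proteins. Lcn2, which encodes the siderophore-binding protein lipocalin 2, rose 15.5-fold, from 8.01 ± 0.65 to 11.97 ± 0.55. Orm1, which encodes orosomucoid 1, rose 11.3-fold, Lrg1, for a leucine-rich glycoprotein, rose by 3.05 log2 units (SE 0.52), and Cp, for the copper carrier ceruloplasmin, rose by 2.83 (SE 0.29). Il24, which encodes a cytokine of the IL-10 family, fell 10.0-fold, from 11.98 ± 0.81 to 8.65 ± 0.67. Serpinb2, which encodes plasminogen activator inhibitor 2, fell by 2.96 (SE 0.42), and Nppb, for B-type natriuretic peptide, differed by -2.33 (SE 0.26). The other large rises were Selenbp1 at 2.75, Arrdc2 at 2.49, Itga10 at 2.47 and the cold-inducible RNA-binding protein gene Cirbp at 2.47. The other large falls were in Ccdc80 (-2.61), Csf2 (-2.17), Ptgs2 (-2.11), the YAP target Ankrd1 (-1.95) and the endothelial lipase gene Lipg (-1.93). The second probe set of Ccdc80 differed by -1.06 (unadjusted p 0.00986), and 1 of 2 others of Lipg, at 5.01 near the filter, by -0.42. The limma adjusted p of these 16 genes lay between 0.00821 and 0.0418.

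In all, 844 of 13090 genes passed an adjusted p of 0.05 with limma, 489 higher and 355 lower at 2 weeks, and 270 of them differed at least 2-fold. At an unadjusted p under 0.05 there were 3088 genes, where chance gives 654.5. Without replicate 1 of the 1-week group no gene passed (smallest adjusted p 0.0657, 1630 genes at an unadjusted p under 0.05), and without its replicate 2 there were 413. Without replicate 1 or replicate 2 of the 2-week vehicle group 115 and 157 genes passed.

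**Figure D2:**
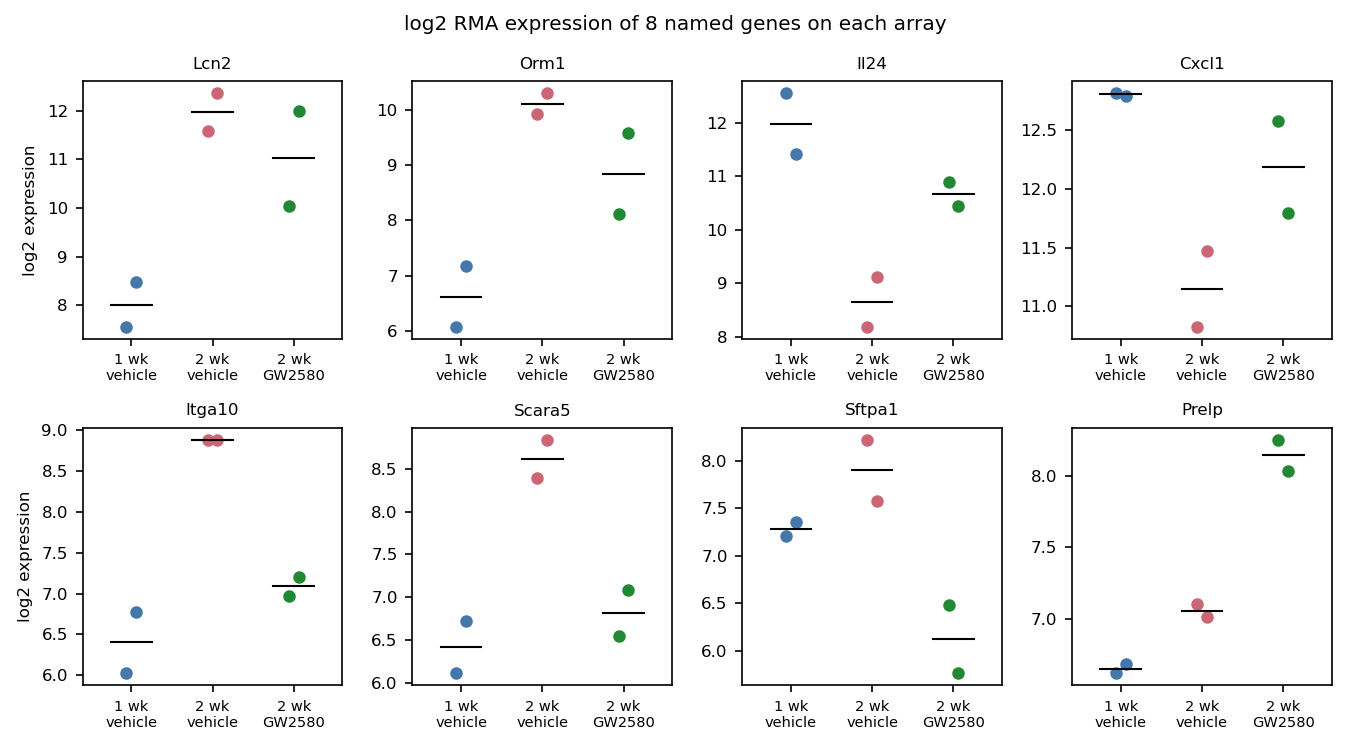
RMA log2 expression of 8 named genes on each array (points, 2 per group; black line, group mean). Lcn2 lies near 8 at 1 week and near 12 at 2 weeks with vehicle, and Itga10 and Scara5 are higher in 2-week vehicle than in both other groups.

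Cell cycle genes were lower at 2 weeks as a group. Of 29 measured, 20 fell and 9 did not pass, and 27 fell when adjusted over the list alone; the median was -0.84 log2. The replication licensing factor Cdc6 fell by 1.42 (SE 0.18), the ubiquitin-conjugating enzyme gene Ube2c by 1.32 (SE 0.16), the mitotic kinase gene Aurka by 1.32 (SE 0.16) and cyclin A2, Ccna2, by 1.20 (SE 0.18). Camera gave the list an adjusted p of 2.83e-22 at the preset correlation and adjusted p = 0.478 with an estimated correlation. Without replicate 2 of the 2-week vehicle group 3 members passed and without replicate 1 of the 1-week group 0, while all 29 differences stayed below 0 in both.

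Immediate early genes and inflammatory cytokines were also lower. Of 17 immediate early genes, which growth signals and stress induce within minutes, 10 fell and 7 did not pass, with 14 falling when adjusted over the list alone (median -0.98). The transcription factor genes Fosb, Atf3 and Egr1 fell by 1.73, 1.67 and 1.57, and Ier3 by 1.37. The camera test gave an adjusted p of 5.88e-11, and adjusted p = 0.508 with an estimated correlation. Of 17 cytokines and NF-kB targets, 6 fell and 11 did not pass, with 10 falling when adjusted over the list alone (median -1.10). Csf2, which encodes GM-CSF, and the prostaglandin synthase gene Ptgs2 stood beside the neutrophil chemoattractant gene Cxcl1, which fell by 1.66 (-0.92 on 1 of 2 other probe sets), and the monocyte chemoattractant gene Ccl2, which fell by 1.48. For this list camera gave an adjusted p of 2.49e-08, and adjusted p = 0.478 with an estimated correlation. In each list 3 members passed without replicate 2 of the 2-week vehicle group, and 0 passed without replicate 1 of the 1-week group, while the medians were -1.03 and -0.91 for immediate early genes and -1.405 and -1.24 for cytokines.

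Cholesterol synthesis genes were lower and hypoxia genes higher at 2 weeks. Of 19 cholesterol synthesis genes, 8 fell and 11 did not pass, with 17 falling when adjusted over the list alone. Cyp51 fell by 1.51, Fdps by 1.46, Msmo1 by 1.16 and Hmgcs1 by 1.07, all enzymes of the pathway; a dim second probe set of Cyp51 differed by 0.01 and 1 of 4 others of Hmgcs1 by -1.68. By camera the adjusted p was 3.73e-11, and adjusted p = 0.508 with an estimated correlation. The cholesterol list mean was 9.77 and 9.25 on the 1-week arrays and 9.07 and 8.64 on the GW2580 arrays. Fibroblast and smooth muscle markers also read higher on replicate 1 of both groups (7.68 and 6.96, 7.12 and 6.53). Whether other cells add to the cholesterol difference was not tested. Of 22 hypoxia response genes, 5 rose and 17 did not pass, with 9 rising and 1 falling when adjusted over the list alone. Bnip3, which acts in mitophagy, rose by 2.01 (SE 0.40), the carbonic anhydrase genes Car12 and Car9 by 1.72 and 1.09, and Ndrg1 by 1.49 (0.91 on 1 of 4 other probe sets). For the hypoxia list camera gave an adjusted p of 0.000268, and adjusted p = 0.684 with an estimated correlation. No member of either list passed without replicate 2 of the 2-week vehicle group or without replicate 1 of the 1-week group, with medians of -0.72 and -0.52 for cholesterol synthesis (-0.72 with all arrays) and 0.49 and 0.42 for hypoxia (0.52).

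Further lists shifted down by camera. Of 12 heat shock genes 3 fell (Hspa1a by 1.68, Dnajb1 by 1.19, Hsph1 by 0.99), 9 did not pass, and 5 fell when adjusted over the list alone (adjusted p 0.000844, and adjusted p = 0.571 with an estimated correlation). Of 18 matrix and protease genes 3 fell (Lamb3 by 1.32, Tnc by 1.24, Plau by 0.57, with -1.52 on its other probe set), 15 did not pass, and 6 fell when adjusted over the list alone (adjusted p 5.26e-05, and adjusted p = 0.438 with an estimated correlation). Of 21 genes of the CSF1 axis and growth factor ligands 4 fell (Csf2, the EGF receptor ligands Hbegf by 1.79 and Tgfa by 0.71, with -0.44 and -0.19 on its other probe sets, and Ccl2) and 17 did not pass. Over the list alone 7 fell and 1 rose (adjusted p 0.000874, and adjusted p = 0.478 with an estimated correlation). Of 20 unfolded protein and ATF4 response genes the stress kinase-like gene Trib3 rose by 0.99 and the chaperone cofactor gene Sdf2l1 fell by 0.91, with 2 rising and 2 falling when adjusted over the list alone. This list's adjusted p was 0.0417, and adjusted p = 0.701 with an estimated correlation. Of 15 mammary epithelium markers the milk protein gene Csn3 fell by 0.95, alone also when adjusted over the list alone (adjusted p 0.00997, and adjusted p = 0.644 with an estimated correlation). Without replicate 2 of the 2-week vehicle group 2 heat shock, 2 matrix, 1 CSF1 axis, 0 unfolded protein and 1 mammary gene passed, and without replicate 1 of the 1-week group 0 of each. In the latter fit the heat shock median of -0.34 became -0.164, and the mammary list (median -0.22, then -0.097) and the unfolded protein list (-0.12, then -0.208) did not pass camera. The unfolded protein list also did not pass it without replicate 2 of the 1-week group (-0.145) or replicate 1 of the 2-week vehicle group (-0.089), where the heat shock median was -0.22.

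Markers of other cell types mostly did not pass. Of 12 fibroblast and smooth muscle markers none passed, over all genes or adjusted over the list alone, and 11 were lower at 2 weeks (median -0.51; Col3a1 -1.71, Lum -0.81). The list passed camera with an adjusted p of 0.00552, and adjusted p = 0.701 with an estimated correlation. It did not pass camera without replicate 1 of the 1-week group, with a median of -0.107 and 8 of 12 lower. Of 15 lung epithelium markers the surfactant protein gene Sftpd rose by 0.89, alone also when adjusted over the list alone, and the list's median of 0.02 and mean of -0.32 differed in sign, with camera's direction down. Sftpd did not pass without replicate 1 of the 1-week group. No member passed among 19 macrophage and monocyte markers (median -0.04, mean 0.01; Cd68 0.98, Laptm5 -0.42 but 0.11 on 1 of 3 others), 8 neutrophil markers (median 0.02; S100a8 1.76, Mmp9 -0.58), 11 lymphocyte and NK cell markers (median -0.07; Cd3d -0.55, Cd2 -0.23), 10 endothelium markers (median -0.06; Plvap -1.20, Tie1 0.86) or 5 erythroid and platelet markers (median -0.16; Alas2 -0.61, Pf4 0.57). When adjusted over the list alone 1 erythroid or platelet marker rose and 1 fell, and 0 of the others passed. Camera's adjusted p for these 6 lists lay between 0.451 and 0.996, and its direction was down for the neutrophil markers, against the median, and for the macrophage markers, against the mean. At a common 75th percentile the medians of the lung epithelium and neutrophil lists were -0.016 and -0.018. The macrophage and endothelium medians were 0.031 and 0.087 without replicate 1 of the 1-week group, and without replicate 1 of the 2-week vehicle group the macrophage and lung epithelium medians were 0.086 and -0.01. Without replicate 2 of the 2-week vehicle group the endothelium median was -0.007 and the erythroid and platelet median -0.105.

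The remaining lists did not pass camera between 1 and 2 weeks (adjusted p 0.158 to 0.996). Of 16 p53 targets 3 rose (Sesn1 by 1.29, Trp53inp1 by 1.07 but 0.24 on its other probe set, Zmat3 by 0.93) and 2 fell (among them Plk3, by 0.79), the same numbers when adjusted over the list alone. Of 16 epithelial-mesenchymal transition and TGF-beta genes the TGF-beta-induced matrix gene Tgfbi rose by 1.54 (SE 0.17); over the list alone 2 rose and 1 fell. Cmpk2 fell by 0.62 among 20 type I interferon genes and Psmb10 by 0.61 among 12 MHC class I genes; adjusted over the list alone, 0 and 1 fell. Without replicate 2 of the 2-week vehicle group 1 p53 target, 1 transition gene and 0 interferon and MHC class I genes passed, and without replicate 1 of the 1-week group 0 of each. No member passed, over all genes or adjusted over the list alone, among 21 ribosome biogenesis and Myc target genes (median 0.01, or -0.021 at a common 75th percentile, with camera's direction down; Odc1 -0.64, and Pes1 0.60 but -0.60 on its other probe set), 11 glycolysis genes (median 0.07; Slc16a3 0.81, Pfkp -0.13), 19 oxidative phosphorylation genes (median 0.08; Cycs -0.45, Uqcrc2 0.27) or 6 MHC class II genes (median 0.07; Ciita 0.19, Cd74 -0.19). The glycolysis median was -0.027 without replicate 1 of the 1-week group and -0.023 without replicate 2 of the 2-week vehicle group, where the ribosome biogenesis median was -0.071.

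Of the genes fixed by name, Myc rose by 0.98 (SE 0.21, limma adjusted p 0.0383) and the pan-leukocyte gene Ptprc fell by 0.61 (SE 0.13, limma adjusted p 0.0387). The receptor gene Csf1r differed by -0.26 (SE 0.20), its ligand genes Csf1 and Il34 by -0.58 (SE 0.17) and -0.62 (SE 0.16), Vegfa by -0.04 (SE 0.23) and Epcam by -0.23 (SE 0.17), none past the threshold.

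**Figure D3:**
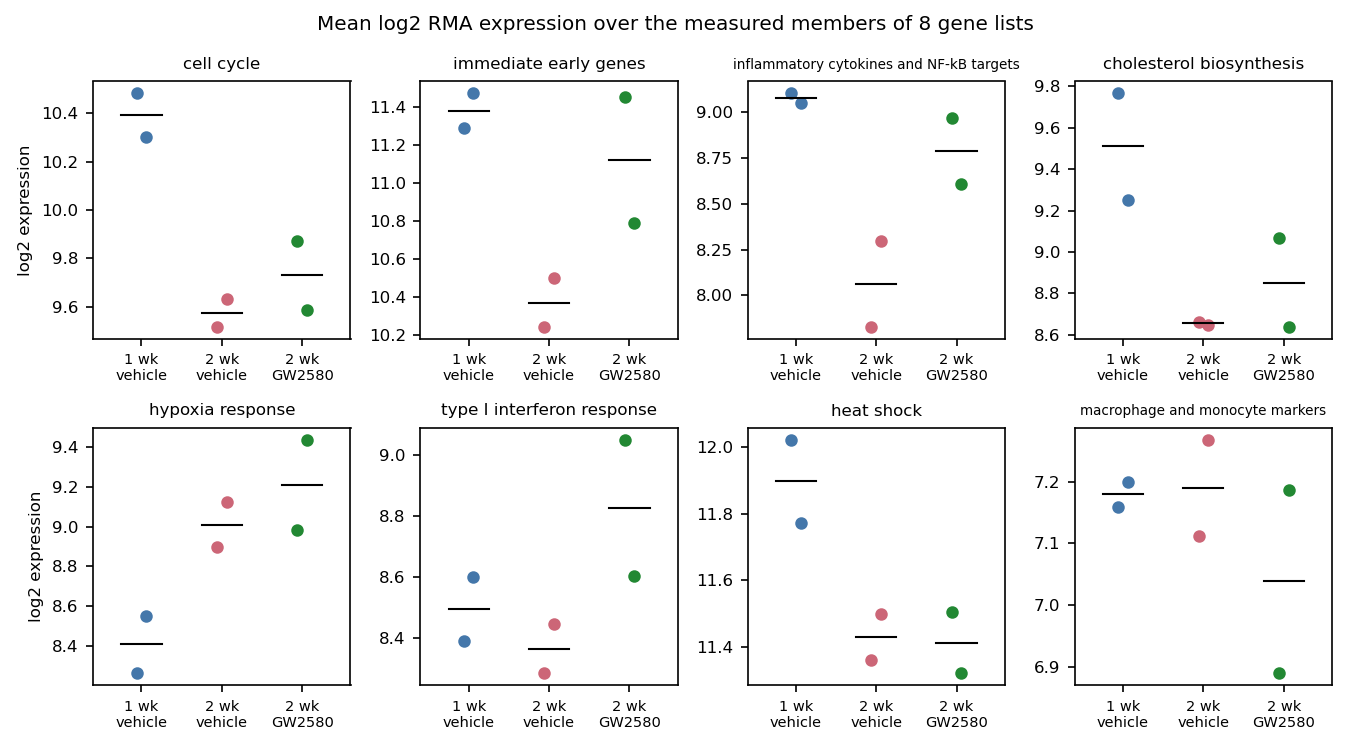
Mean RMA log2 expression over the measured members of 8 gene lists on each array (points, 2 per group; black line, group mean). Cell cycle and heat shock genes are lower on all 4 arrays of 2 weeks than on both arrays of 1 week, while immediate early genes and cytokines are lowest on the 2-week vehicle arrays.

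The comparison of GW2580 with vehicle at 2 weeks addressed the effect of CSF1 receptor inhibition on the tumour cells. The scavenger receptor gene Scara5 fell by 1.80 (SE 0.26) on its brighter probe set, while the other, at 5.04 near the filter, differed by 0.08. Falls were also seen in the integrin subunit gene Itga10, which fell by 1.79 (SE 0.23), and the bile acid transporter family gene Slc10a6, which fell by 1.71 (SE 0.23). The surfactant protein genes Sftpa1 and Sftpd, markers of lung epithelium, fell by 1.78 (SE 0.27) and 1.12 (SE 0.16). Among the rises, Kcnh2, which encodes a potassium channel, went from 6.56 ± 0.51 to 8.05 ± 0.02, the matrix protein gene Prelp rose by 1.09 (SE 0.13), and the EGR corepressor gene Nab2 rose by 1.02 (SE 0.13). Further rises were C130075A20Rik at 1.65, Ikzf2 at 1.12, Csrnp1 at 0.97, Chid1 at 0.93 and Sdf2l1 at 0.87, and further falls were Tent5b (-1.66), Hrct1 (-1.66), Cox7c (-1.49) and Sft2d3 (-1.46). The second probe set of Chid1, nearly as bright (7.44 against 7.83), differed by 0.33 and that of Csrnp1 by 0.28 (unadjusted p 0.0731 and 0.15). The limma adjusted p of these genes lay between 0.0347 and 0.0489.

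In all, 48 genes passed an adjusted p of 0.05 with limma, 9 higher and 39 lower with GW2580, and 2352 had an unadjusted p under 0.05, where chance gives 654.5. On all probe sets, where those without a gene name also count, 111 passed, 59 higher and 52 lower. No gene passed when only the 4 arrays compared were fitted (smallest adjusted p 0.0835, 2120 genes at an unadjusted p under 0.05), nor without either 1-week array (the same values). None passed without replicate 2 of the 2-week vehicle group (1513 at an unadjusted p under 0.05) or replicate 1 of GW2580 (1596), while 6 passed without replicate 1 of the 2-week vehicle group and 167 without replicate 2 of GW2580.

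None of the genes fixed by name passed. Csf1r differed by -0.02 (SE 0.20), Csf1 by 0.58 (SE 0.17), Il34 by 0.35 (SE 0.16), Myc by -0.62 (SE 0.21), Vegfa by 1.15 (SE 0.23, limma adjusted p 0.079), Epcam by 0.32 (SE 0.17) and Ptprc by -0.12 (SE 0.13).

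Immediate early genes, cytokines and interferon genes were higher with GW2580 as groups, although no member passed over all genes. All 17 immediate early genes had positive differences (median 0.69; Egr1 1.40, Dusp1 0.63), and 11 rose when adjusted over the list alone. Camera's adjusted p was 1.31e-10, and adjusted p = 0.492 with an estimated correlation. Of 17 cytokines and NF-kB targets 16 were positive (median 0.69; Ptgs2 1.56, Ccl7 1.09), and 9 rose when adjusted over the list alone. For cytokines camera gave an adjusted p of 2.56e-08, and adjusted p = 0.492 with an estimated correlation. Of 20 type I interferon genes 18 were positive (median 0.50; Oasl2 1.05, Cmpk2 0.63), and 7 rose when adjusted over the list alone. For interferon genes camera gave an adjusted p of 1.67e-08, and adjusted p = 0.492 with an estimated correlation. The 2 GW2580 arrays differed in these groups: the list mean was 11.46 and 10.79 for immediate early genes, 8.97 and 8.61 for cytokines, and 9.05 and 8.60 for interferon genes on replicates 1 and 2. Lung epithelium markers (7.30 and 6.53) and fibroblast and smooth muscle markers (7.12 and 6.53) were likewise higher on replicate 1. Without replicate 1 of GW2580 the median was 0.336 for immediate early genes and 0.243 for interferon genes, and without replicate 2 it was 1.139 for immediate early genes.

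Smaller upward shifts passed camera in 9 lists. No member of 8 of them passed over all genes: 22 hypoxia genes (median 0.16; Vegfa 1.15, Car12 -1.24), 11 glycolysis genes (median 0.23; Pfkl 0.96, Hk2 0.66), 12 MHC class I genes (median 0.17; Psmb9 0.69, Psmb10 0.65), 29 cell cycle genes (median 0.12; Ube2c 0.60, Plk1 0.47), 15 mammary epithelium markers (median 0.18; Csn3 0.90, Elf3 0.42), 19 cholesterol synthesis genes (median 0.23; Hsd17b7 -0.65, Insig1 0.47), 18 matrix and protease genes (median 0.11; Mmp13 1.97, Plau 0.55) and 21 genes of the CSF1 axis and ligands (median 0.16; Vegfa, Csf1). In the unfolded protein and ATF4 list Sdf2l1 rose and 19 did not pass (median 0.09). Their camera adjusted p lay between 0.0014 and 0.04, and each lost its call, with adjusted p = 0.492 to adjusted p = 0.551 with an estimated correlation. When adjusted over the list alone, 3 rose and 1 fell for hypoxia, 2 rose for matrix and for unfolded protein genes, 1 rose for MHC class I, mammary markers and CSF1 axis each, and 0 passed for glycolysis, cell cycle and cholesterol synthesis. Without replicate 1 of GW2580 the cell cycle (median -0.007), cholesterol (0.055), MHC class I (0.046) and mammary (0.198) lists did not pass camera, and the medians of hypoxia, glycolysis and CSF1 axis genes were 0.333, 0.355 and 0.275. Without its replicate 2 the hypoxia (0.101), glycolysis (0.10) and unfolded protein (0.059) lists did not pass, and the cell cycle, MHC class I, cholesterol and CSF1 axis medians were 0.333, 0.323, 0.355 and 0.098. Without replicate 1 of the 2-week vehicle group the hypoxia (0.105), MHC class I (0.122) and unfolded protein (0.037) lists did not pass, and the cell cycle median was 0.069. Without replicate 2 of that group the medians of hypoxia, MHC class I and unfolded protein genes were 0.304, 0.277 and 0.17, and 0 members of the last passed.

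Lists of 2 kinds shifted down by camera. Of 21 ribosome biogenesis and Myc target genes 20 were negative (median -0.26; Gnl3 -0.61, and Pes1 -0.63 but 0.45 on its other probe set), and 1 fell when adjusted over the list alone (adjusted p 0.00145, and adjusted p = 0.492 with an estimated correlation). Of 16 p53 targets 13 were negative (median -0.38; Aen -0.74 but 0.36 on the dimmest of 3 others, Ccng1 -0.53), and 3 fell when adjusted over the list alone (adjusted p 0.0322, and adjusted p = 0.492 with an estimated correlation). No member of either passed over all genes. The p53 list did not pass camera without replicate 1 of the 2-week vehicle group (median -0.264), replicate 1 of GW2580 (-0.277) or replicate 2 of GW2580 (-0.353). The ribosome biogenesis median was -0.149 without replicate 1 of GW2580.

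Markers of macrophages, the cells that carry the receptor, averaged 7.11 and 7.27 on the 2 vehicle arrays and 6.89 and 7.19 on the 2 GW2580 arrays. Of 19 macrophage and monocyte markers 15 were negative (median -0.11; the complement genes C1qc -0.58 and C1qa -0.73), and 0 passed, over all genes or adjusted over the list alone. Without replicate 2 of the 2-week vehicle group 10 were positive and 9 negative (median 0.005), without replicate 1 of GW2580 the median was 0.009, and without its replicate 2 it was -0.273. Of 15 lung epithelium markers Sftpa1 and Sftpd fell and 13 did not pass, with 6 falling when adjusted over the list alone; without replicate 2 of the 2-week vehicle group 0 passed over all genes. Scgb1a1, the club cell secretory protein gene of that list, chosen after its values were seen, spread from 6.49 to 11.31 over the 6 arrays and read 10.91 and 7.59 on the 2 GW2580 arrays. No member passed among 8 neutrophil markers (median 0.10, mean -0.13, camera's direction up; Mmp9 0.58, S100a8 -1.80), 11 lymphocyte and NK cell markers (median 0.07; Prf1 -0.33, Cd2 0.28), 10 endothelium markers (median -0.03, mean 0.10, camera's direction up; Plvap 1.54, Tie1 -0.52), 12 fibroblast and smooth muscle markers (median 0.06; Pdgfra -0.62 but 0.27 on a dimmer probe set, Mfap4 0.58) or 5 erythroid and platelet markers (median 0.20; Alas2 0.41, Itga2b 0.21). Over the list alone 1 endothelium marker rose, 1 fibroblast or smooth muscle marker rose and 1 fell, and 0 of the others passed. Camera's adjusted p for these 7 lists lay between 0.0677 and 0.496. The fibroblast median was -0.227 without replicate 1 of GW2580, and the endothelium median was 0.019 without replicate 1 of the 2-week vehicle group and 0.022 without replicate 2 of GW2580.

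The last 4 lists did not pass camera with GW2580 (adjusted p 0.0513 to 0.99), and no member passed over all genes. They were 19 oxidative phosphorylation genes (median -0.11; Ndufv1 -0.33, Ndufs1 -0.28), 6 MHC class II genes (median -0.17; Ciita -0.56, H2-Aa -0.42), 16 epithelial-mesenchymal transition and TGF-beta genes (median 0.10; the fibronectin gene Fn1 1.10, Snai1 0.66) and 12 heat shock genes (median -0.09, with camera's direction up; Hspa4l -0.51 but 0.35 and 0.08 on 2 of 4 others, Hspa1a 0.62). When adjusted over the list alone 3 rose and 1 fell in the transition list, 1 fell in MHC class II, and 0 passed in the others.

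Genes that differed between 1 and 2 weeks mostly lay on the opposite side with GW2580. Of 39 genes lower with GW2580, 32 were among those higher at 2 weeks with vehicle, Itga10, Scara5 and Slc10a6 among them, where independent lists would share 1.46. Of 9 genes higher with GW2580, 5 were among those lower at 2 weeks, where independent lists would share 0.24, and no gene was called in the same direction in both. Simulated unchanged groups shared at most 1 call, though they held 0.65 time calls on average. Of the 844 genes called over time 88.2% had the opposite sign with GW2580, but the 844 first-ranked genes of unchanged groups sharing the vehicle arrays did so at 87.6% on average. With each vehicle array in a single comparison the share was 84.8% or 90.3%, against 80.3% to 86.5% in unchanged groups; the genes were ranked with both arrays.

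Across the 13090 genes, which are not independent replicates, Pearson's r between the time and the inhibitor difference was -0.615 and Spearman's rho -0.573. Simulated unchanged groups, whose genes varied independently of each other, gave r of -0.519 to -0.473. The covariance was -0.0722, against -0.0137 simulated, a difference of -0.0585. Without replicate 1 of GW2580 r was -0.426, within the -0.436 to -0.386 simulated for those arrays, while the covariance was -0.0477 against -0.0149 at the lowest. Without replicate 1 or 2 of the 2-week vehicle group r was -0.65 and -0.664, also within the simulated ranges (-0.684 to -0.646 and -0.679 to -0.648), and the covariance was -0.086 and -0.0891 against -0.0294 and -0.0289 at the lowest. With each 2-week vehicle array used in only a single comparison, r was -0.396 or -0.46, against -0.044 to 0.036 in simulated unchanged groups split in this way. In that split without replicate 1 of GW2580, r was -0.226 or -0.281, against -0.041 at the lowest. Each side of that split holds 1 vehicle array. How far the shared arrays raise the overlap of calls was not tested.

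**Figure D4:**
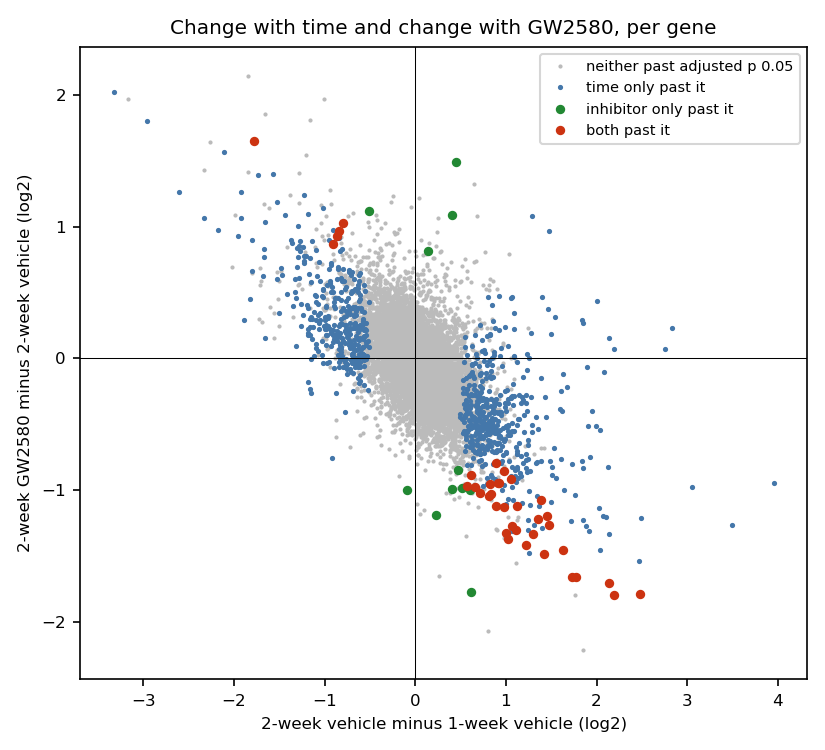
Log2 difference between GW2580 and vehicle at 2 weeks (vertical axis) against the log2 difference between 2-week and 1-week vehicle (horizontal axis), a point per tested gene, coloured by the comparison in which it passed an adjusted p of 0.05. Of the points called in both, 32 lie at lower right and 5 at upper left; both axes hold the 2-week vehicle arrays.

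The comparison of GW2580 at 2 weeks with vehicle at 1 week held 67 genes past an adjusted p of 0.05 with limma, 47 higher and 20 lower. Cp rose by 3.06 (SE 0.29), Selenbp1 by 2.82 (SE 0.41) and the galectin gene Lgals2 by 2.44 (SE 0.19) on a probe set of shared sequence. The other probe set of Lgals2 differed by 0.37, and without shared-sequence probe sets Lgals2 did not pass (0.366, adjusted p 0.23); 1 of 6 others of Cp differed by 1.70. Serpinb9g fell by 1.67 (SE 0.20), the glutathione transferase gene Gstt4 by 1.60 (SE 0.14) and the kallikrein gene Klk6 fell 2.83-fold. Of the 47 higher genes 33 were also higher at 2 weeks with vehicle, and of the 20 lower genes 16 were also lower, where independent lists would share 1.76 and 0.54. The 1-week arrays are common to both comparisons, and how far this raises the overlap was not tested. Camera called 11 lists, 5 up and 6 down, and 0 with an estimated correlation. Besides those described below, interferon (median 0.34, 19 of 20 positive), MHC class I (0.21, 12 of 12), glycolysis (0.295, 11 of 11) and transition genes (0.11, 12 of 16) were higher. Cholesterol synthesis (-0.62, 19 of 19 negative), heat shock (-0.405, 12 of 12) and ribosome biogenesis genes (-0.27, 18 of 21) were lower. All 29 cell cycle genes were lower (median -0.67, camera adjusted p 1.43e-19, and adjusted p = 0.562 with an estimated correlation), and 29 fell when adjusted over the list alone, but 0 over all genes. Hypoxia genes were higher (median 0.94), with 1 rising over all genes, a call lost in 4 of the 6 fits without an array, and 15 rising and 1 falling when adjusted over the list alone (adjusted p 1.29e-11, and adjusted p = 0.562 with an estimated correlation). Fibroblast and smooth muscle markers were lower too (median -0.53, 10 of 12 negative, camera adjusted p 0.0155, and adjusted p = 0.683 with an estimated correlation), as were lung epithelium markers (median -0.27, 12 of 15 negative, 0.0338, and adjusted p = 0.562 with an estimated correlation). Over all genes 0 of both passed; over the list alone 1 fibroblast marker rose and 3 fell, and 4 lung epithelium markers fell. Neither list passed camera without replicate 1 of the 1-week group (medians -0.325 and -0.285) or replicate 2 of GW2580 (-0.286 and -0.089), and the medians were -0.84 and -0.42 without replicate 2 of the 1-week group. Without replicate 1 of the 1-week group no gene passed with limma (1104 at an unadjusted p under 0.05), and none without replicate 2 of GW2580 (2159), while 169 passed without replicate 1 of GW2580. Without replicate 2 of the 1-week group 38 passed, and without either 2-week vehicle array 24.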

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

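All explanations below were written and their tests chosen after the results were seen, although the fits with 1 vehicle array per comparison were planned; the test of leukocytes was split by cell type after a joint test decided nothing, other lung cells and a rule that markers near the median signal exclude nothing were added later, and the test of 5' loss for the opposite relation was changed after a first result, as stated there. The control probe sets, which no comparison used, differed on single arrays: on replicate 2 of the 2-week vehicle group the 3' minus 5' difference was 1.20 for beta-actin, 0.92 for Gapdh and 2.84 for the thr spike, against at most 0.50, -0.10 and 1.61 elsewhere. The BioB hybridization control read 10.03 on replicate 1 of the 1-week group, above the 8.74 to 9.02 of the other 5 arrays. Of 3914 tested probe sets without a single gene symbol, 204 passed over time (47 higher, 157 lower) and 51 with GW2580 (48 higher, 3 lower), and 43 were lower over time and higher with GW2580.

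Immediate early genes and cytokines were lower in the 2-week vehicle arrays than in both other groups. Loss of 5' signal on replicate 2 of that group is argued against, since replicate 1 alone, with ordinary 3' minus 5' values, lay at -1.19 from the 1-week arrays and at -0.92 from the GW2580 arrays over both lists. Macrophages carried through the GFP sort, which should remove them, could raise cytokine signal. However, the 19 macrophage markers, none of which stood in another list, changed by -0.15 on average with GW2580, while the 2 lists rose by 0.74. Upper bounds in this section are the mean plus 2 SE over the genes of a list, so they leave out the spread between arrays. For macrophages the bound was -0.02. Without replicate 1 or 2 of GW2580 it was 0.148 or -0.124 and the rise 0.482 or 0.995. The macrophage list mean was 7.11 and 7.27 on the vehicle arrays and 6.89 and 7.19 on the GW2580 arrays. No rise like that of the 2 lists was seen, but 2 arrays per group set no firm limit. The most abundant markers, Cd14 and Cd68, changed by -0.02 and -0.43. Neutrophils, lymphocytes and other lung cells cannot be told apart from a change in the tumour cells: upper bounds were 0.42 over 8 neutrophil markers (the most abundant, S100a8 and S100a9, changed by -1.80 and -0.75), 0.19 over 11 lymphocyte markers (0.328 without replicate 2 of GW2580), lists only 0.75 and 0.40 above the array median, and 0.49 for lung epithelium; without replicate 2 of GW2580 the bound was 1.103 for lung epithelium and 0.813 for fibroblasts, and without replicate 1, where both read higher (7.30 against 6.53, and 7.12 against 6.53) as the 2 lists did, -0.045 and -0.046. Handling before lysis also stays open, since heat shock genes changed by -0.468 over time but by -0.016 with GW2580. Of these 12 genes 4 were positive and 8 negative with GW2580. The 3 called over time, Hspa1a, Dnajb1 and Hsph1, differed by 0.62, 0.38 and 0.4 with GW2580, though both comparisons hold the 2-week vehicle arrays. The effect of the inhibitor itself stays among the open explanations.

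The inhibitor difference ran opposite to the time difference across genes. Noise of the shared vehicle arrays is argued against as the whole of it. With each array in a single comparison, where shared noise gives 0 on average, r was -0.396 or -0.46 (lowest simulated -0.044). Without replicate 1 of GW2580 it was -0.226 or -0.281. However, simulated genes varied independently, so the simulated range may be too narrow for genes that move together. Noise in such genes on arrays that are not shared is therefore not excluded. Deviations of same-numbered arrays of different groups correlated at up to 0.292 across genes. With the arrays shared, r lay within its simulated range when replicate 1 of GW2580 (-0.426) or either 2-week vehicle array (-0.65 and -0.664) was left out. With the same limit for genes that move together, loss of 5' signal on replicate 2 of the 2-week vehicle group is argued against as the whole of it. The same fits serve as the test, since that array stands in 1 comparison only there. This test replaced 2 others: without that array the correlation, -0.664, lay within the range simulated with 1 shared array (lowest -0.682) and decided nothing, and the covariance, -0.0891, tried next, lay below its lowest simulated -0.0289. A batch common to the 2-week vehicle arrays cannot be told apart from an inhibitor effect, which stays open, because the labels give no batch; the spike level differed from that of GW2580 by -0.15, with overlapping arrays.

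Cell cycle genes were lower at 2 weeks. More non-tumour cells of all types in the later sort would raise the markers of every type, but more of 1 type need raise only its own. Fibroblast and smooth muscle markers changed by -0.58 (Col3a1 and Col1a2, their most abundant, by -1.71 and -1.52). Without replicate 1 of the 1-week group they changed by -0.22, with an upper bound of 0.013. Neutrophil markers changed by 0.249 on average, 5 up and 3 down (S100a8 1.76, S100a9 1.09). Macrophage markers changed by 0.01, 9 up and 10 down (Cd68 0.98, Cd14 0.06), and none of both lists was called. The pan-leukocyte gene Ptprc, in neither list, was called lower at 2 weeks. More non-tumour cells thus cannot be told apart from a change in the tumour cells. Loss of 5' signal is argued against by replicate 1 alone, at -0.87 from 1 week, beside -0.76 for replicate 2. A labelling batch that follows the week may contribute and cannot be told apart from time, as the spike level of the 2-week arrays was higher by 0.49 with no overlap. A change of the tumour cells with time stays open and untested.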

How the results depend on the processing

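The list counts without the 2 arrays whose control probe sets stand apart, the list medians under other scalings or without each array, and the simulations for each array left out were chosen after seeing the data. The number of genes called was 844 over time, 48 with GW2580 and 67 for GW2580 against 1 week. Over time it moved to 1316 with array weights and 270 with a 2-fold minimum, and to between 0 and 1059 with an array left out. With GW2580 it moved to 74 with no filter on dim genes, 75 with an intensity trend, 131 with a trend and robust prior, 0 on only the 4 arrays (2120 at an unadjusted p under 0.05 with limma), 15 with array weights, 31 with a 2-fold minimum and 111 on all probe sets, and to between 0 and 167 with an array left out. Against 1 week it moved to 139 with trend and robust prior, 24 on 4 arrays, 32 on all probe sets, and between 0 and 169 with an array left out. Fits without an array also have fewer residual degrees of freedom; beyond that, and the construction of a stricter threshold, the cause was not tested.

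Replicate numbers were not taken to pair the arrays. Deviations of same-numbered arrays correlated across genes at 0.002 between the vehicle groups and 0.009 between 2-week vehicle and GW2580. Between 1-week vehicle and GW2580 the correlation was 0.292, so those deviations were partly shared. With replicate number as a block the counts were 1223, 154 and 182.

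Camera called 11, 14 and 11 lists. With an estimated correlation it called 0 in each comparison (1, 1 and 0 at an unadjusted p under 0.05), and fry 0 (6, 1 and 4). Against the preset 0.01, the estimate was 0.615 for cell cycle and 0.657 for immediate early genes. A higher correlation widens the assumed spread of a list mean by construction. For matrix and protease genes, at -0.004, the unadjusted camera p over time still went from 1.05e-05 to 0.0175. The correlation is thus not the whole cause, and the rest was not tested. The correlation between the time and the inhibitor difference, -0.615, ranged from -0.664 (without replicate 2 of the 2-week vehicle group) to -0.426 (without replicate 1 of GW2580, simulated -0.436 to -0.386) and was -0.396 and -0.46 with split vehicle arrays, which removes the shared noise by construction.

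Among the genes named by the rule, the differences that changed sign were all of genes not called. Over time, Laptm5 was 0.112 without shared-sequence probe sets, Pes1 -0.002 and Vegfa 0.219 as a mean over probe sets, and Vegfa 0.038 with an array left out. With GW2580, H2-Aa was 0.005 with an array left out, Epcam -0.007 without shared-sequence probe sets, and Csf1r 0.009 at a common 75th percentile, 0.02 as a mean over probe sets and 0.011 and 0.291 with an array left out; the cause was not tested. With an array left out Vegfa ranged from -0.127 over time, and H2-Aa and Csf1r from -0.852 and -0.325 with GW2580. Each called gene named by the rule gave a result under each alternative that tested it, and the direction of other called genes was not checked. Of these results, 744 kept their direction and side of the threshold and 184 their direction only over time. With GW2580 the numbers were 166 and 120, and against 1 week 75 and 24. For called lists, with direction taken from camera, these numbers were 91 and 30 over time and 110 and 44 with GW2580; the median changed sign once, to -0.007 for cell cycle genes without replicate 1 of GW2580. Under quantile normalisation and a common 75th percentile the list medians kept their sign, except at the 75th percentile over time for lung epithelium, neutrophil and ribosome biogenesis genes, and with GW2580 for endothelium markers, at 0. The filter stood at 4.97, and array signals near it hold more background.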

Other observations

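The families below were grouped by symbol and tested, also without each array, only after the data were seen. Of 150 groups of at least 10 tested genes sharing a symbol stem, 6 passed camera over time and 1, the Snhg genes, with GW2580. Snhg genes are non-coding host genes of small nucleolar RNAs. All 12 were higher at 2 weeks than at 1 week with vehicle (median 0.69) and 7 rose, led by Snhg7 at 1.39, Snhg6 at 1.12 and Snhg4 at 1.12. With GW2580 11 of the 12 were lower than with vehicle (median -0.51) and 2 fell, Snhg4 by 1.12 and Snhg7 by 1.08. Camera's adjusted p was 2.25e-05 over time and 0.000631 with GW2580, and adjusted p = 0.987 and adjusted p = 0.975 with an estimated correlation. At a common 75th percentile 11 of 12 were higher over time, and after quantile normalisation 10 of 12 were lower with GW2580. Both differences hold the 2-week vehicle arrays, so the opposite directions are not independent.

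Of 252 zinc finger genes with Zfp symbols 183 were higher at 2 weeks (median 0.17), 17 rose and 2 fell (camera adjusted p 0.00178, and adjusted p = 0.987 with an estimated correlation). At the 75th percentile 172 of the 252 were higher. The other 4 were lower over time, under both other scalings too, and each had adjusted p = 0.987 with an estimated correlation. They were 10 Serpinb protease inhibitor genes (median -0.53, 5 fell, camera adjusted p 0.00191), 10 Mcm genes (median -0.44, 1 fell, 0.0113), 31 keratin genes (median -0.18, 1 fell, 0.0236) and 31 collagen genes with Col symbols (median -0.11, 2 fell, 0.0323). With a filter at the 60th percentile the median of the 18 collagen genes left was -0.632. Without an array of either vehicle group the collagen median ranged from -0.135 to -0.251 (without replicate 2 of the 1-week group), and the keratin median was -0.123 without replicate 1 of the 2-week vehicle group and -0.028 without replicate 1 of the 1-week group. Fibroblast and smooth muscle markers, which include the collagen genes Col3a1 and Col1a2, were lower as well, by -0.578 on average and by -0.22 without that array.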
